A study of Mus musculus with 6 samples.

How the data were processed

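Liver RNA from male mice on a high-fat diet was measured in 6 libraries, 3 from vehicle and 3 from ONX-0914 treated animals. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched and fragmented, and paired reads of 150 bases were sequenced on an Illumina instrument. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.11, HISAT2 2.0.1, featureCounts 1.6.0 and edgeR, with the builds GRCm38 and mm10. They give no role or order of these tools, and the annotation is not given in the sources used here.

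The deposited matrix holds FPKM values made by the authors for 22851 genes, rounded to 2 decimals. The unit is read from the values, which are not whole, differ in their sums between libraries and get smaller with gene length. Whether reads or fragments were counted, and the scaling, are not stated. Columns were matched to samples by name. The tests had been planned for counts; since the matrix holds a normalized unit, the planned fallback was used.

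Genes with a value above 1 in at least 3 libraries (10743 genes) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, no block and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes on this scale understate the change of low genes. Values near 0 carry few reads, and relative depth was estimated from the whole-number ratios of low values between libraries.

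A set of 38 gene lists fixed before the data were examined covers pathways, complexes, zones, cell types and quality signs, and 37 had at least 5 tested members. They were tested with camera, two-sided, with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether a list moves one way. With an estimated correlation camera has few degrees of freedom in 6 libraries, so a missing call there is weak evidence against a list. Since camera is competitive, a list can be called up while its median is at or below 0. Ribosomal protein genes, Mup, Saa and Cyp4a families share reads between near-identical copies and are uncertain.

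Genes named are Psmb8, Psmb9, Psmb10, Psmb5, Psmb6, Psmb7, Hdac2 and Srebf1. Named too are the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 and no overlap between groups, and up to 4 called members per list. The rule was set before the data were examined. Not all of the genes it selects are printed.

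Alternatives to the count of genes comprised 10 planned settings and 9 added after the data were seen. Those added were 4 scalings (median ratio, upper quartile, equal sums, quantile), removal of the length trend alone or with GC content, ONX-0914 3 alone, a robust fit and a filter on the mean. For the length trend, each library's deviation from the vehicle mean was smoothed over the longest protein-coding transcript of GENCODE M21, known for 99.4% of tested genes. It also centres each library, so it fixes part of the balance between higher and lower genes.

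The fit was tested on simulated data with the 10743 genes, 50 genes changed per size. It recovered 0% of changes of 0.5 on the log2 scale, 36% of changes of 1, 94% of changes of 2 and 100% of changes of 3, and called 4 unchanged genes. With a length trend added it called 8304 genes, and 120 after the correction. That trend was smooth, the same in each treated library and built on the lengths that the correction uses. Its removal was thus built in and does not show how well the correction works on the real libraries. Far fewer genes changed in the simulation than were called in the data, so the shares recovered do not carry over. Falls drawn for genes with low values were turned into rises.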

Results

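Liver RNA was sequenced from male C57BL/6J mice, an inbred laboratory strain, kept on a high-fat diet. One group received vehicle and the other ONX-0914, an inhibitor of PSMB8, the chymotrypsin-like subunit of the immunoproteasome. The drug was injected under the skin at 10 mg/kg every other day for 6 weeks. There were 3 libraries per group, vehicle 1, 2 and 4 and ONX-0914 1, 3 and 4, whereas the design text gives 2 animals per group. Since it is not stated which libraries come from separate animals, p-values measure the spread between these libraries. The deposited FPKM values summed to between 993264 and 1074027 per vehicle library and between 1041391 and 1247789 per treated library. Read totals were not given, so the absolute depth is unknown. Low values gave relative depths of 1.00, 1.28 and 1.12 for vehicle 1, 2 and 4, and of 1.01, 0.859 and 0.901 for ONX-0914 1, 3 and 4. ONX-0914 3 stood apart from the other treated libraries. On the first principal component, with 77.3% of the variance, it lay at 10.6, against 73.95 and 67.81 for ONX-0914 1 and 4 and -56.07, -49.09 and -47.2 for vehicle 1, 2 and 4. Its values correlated at 0.9262, 0.9367 and 0.9261 with vehicle 1, 2 and 4 and at 0.9149 and 0.9247 with ONX-0914 1 and 4. Where it is set alone against vehicle below, the spread comes from the 3 vehicle libraries only and the lone library is assumed to vary as they do.

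The comparison of treated with vehicle livers asks how the drug changes liver transcripts, and the study's title names fat in the liver, HDAC2, SREBP1 and PSMB8. Of 25 de novo lipogenesis genes 22 fell. Scd1, which encodes the desaturase that makes oleate, averaged 4580 ± 1498 FPKM (SD, n = 3) with vehicle and 89.7 ± 28.7 (n = 3) with ONX-0914, a log2 fold change of -5.66 (SE 0.30, limma adjusted p = 8.71e-05). Sdf2l1, a chaperone cofactor gene, and Hp, the haptoglobin gene, rose, and each of the 24 endothelial markers tested fell. The transcripts of Psmb8, Hdac2 and Srebf1 themselves did not pass the test over the 6 libraries. The median gene of the 10743 tested had a log2 fold change of -0.64, so many values are also given scaled by median ratio (each library divided by the median of its ratios to the geometric mean). That leaves a median of -0.17. As deposited, 4673 of the 10743 genes were called lower and 275 higher, so falls counted in a list are to be read beside that share.

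Of 25 de novo lipogenesis genes, 22 fell over all genes tested, 23 adjusted over the list alone, and none rose in either. The list's median log2 fold change was -2.41, and -1.97 scaled by median ratio, where 18 members fell. With each library's transcript-length trend removed, described below, the median was -1.68 and 18 fell. Camera, which compares a list with all other genes, gave an adjusted p of 3.76e-07 with the preset correlation and an adjusted p = 0.34 with an estimated correlation. Beside Scd1 (-5.06 scaled by median ratio), Elovl5, a fatty acid elongase, had a log2 fold change of -3.65 (SE 0.50, limma adjusted p = 0.0017) and of -3.08 scaled by median ratio. Gpam, which starts triglyceride synthesis, had a log2 fold change of -3.40 (-2.86 scaled by median ratio), and Pklr, liver pyruvate kinase, one of -3.06 (-2.48). Srebf1 itself, the gene of SREBP1, was 72.6, 57.9 and 41.5 FPKM in vehicle 1, 2 and 4 and 28.8, 12.9 and 49.3 in ONX-0914 1, 3 and 4, a log2 fold change of -1.05 (SE 0.43, limma adjusted p = 0.0686). It was -0.46 scaled by median ratio (adjusted p = 0.497) and -0.16 with the length trend removed (adjusted p = 0.852). With ONX-0914 3 alone against vehicle Srebf1 passed, at -2.04 (adjusted p = 0.00402).

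Of 35 fatty acid oxidation and ketogenesis genes, 25 fell and 1 rose over all genes, 26 and 1 adjusted over the list alone, with a median log2 fold change of -1.114 (-0.53 scaled by median ratio, where 15 fell and 1 rose, and -0.47 with the length trend removed, where 13 fell and none rose). The camera adjusted p was 0.013, and adjusted p = 0.741 with an estimated correlation. Acsl1, which activates long-chain fatty acids, had a log2 fold change of -3.32 (SE 0.40, limma adjusted p = 0.0014) and of -2.73 scaled by median ratio. Cyp4a14 and Cyp4a10, fatty acid omega-hydroxylases induced by PPARα, had log2 fold changes of -4.42 (SE 0.93) and -4.16 (SE 0.86), and of -3.96 and -3.69 scaled by median ratio. These are close paralogs whose reads the counting could split. Cyp4a14 was at 153, 19.6 and 160 FPKM in vehicle 1, 2 and 4, and Cyp4a10 at 98.0, 22.1 and 175. Both were thus low in vehicle 2 already, near their 13.6 and 14.1 FPKM in ONX-0914 3. In ONX-0914 3 alone against vehicle they were at -2.45 and -2.30 (limma adjusted p = 0.111 and 0.0986). Cd36, a fatty acid transporter, averaged 114 ± 26.2 FPKM (n = 3) with vehicle and 16.7 ± 2.51 (n = 3) with ONX-0914, a log2 fold change of -2.68 (-2.10 scaled by median ratio). Of 31 genes of lipid uptake, storage and export, 15 fell and none rose over all genes, 16 and none adjusted over the list alone, but camera did not call the list (adjusted p = 0.295). In median-ratio scaled values 7 fell and 2 rose, and with the length trend removed 7 fell and 1 rose (camera adjusted p = 0.0463, or adjusted p = 0.4 with an estimated correlation). Of 27 cholesterol synthesis genes 14 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 0.686). These were 6 and 2 scaled by median ratio and 4 and 2 with the length trend removed.

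The glycogen-targeting genes Ppp1r3c and Ppp1r3b were among the 10 largest falls, with log2 fold changes of -3.86 (SE 0.37) and -3.66 (SE 0.48), and of -3.45 and -3.12 scaled by median ratio. Adipor2, an adiponectin receptor, went from 177 ± 7.75 to 15.9 ± 12.1 FPKM (n = 3 each), and Rgs16, a regulator of G protein signalling, from 24.1 ± 6.42 to 1.36 ± 2.17 (n = 3 each).

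**Figure D1:**
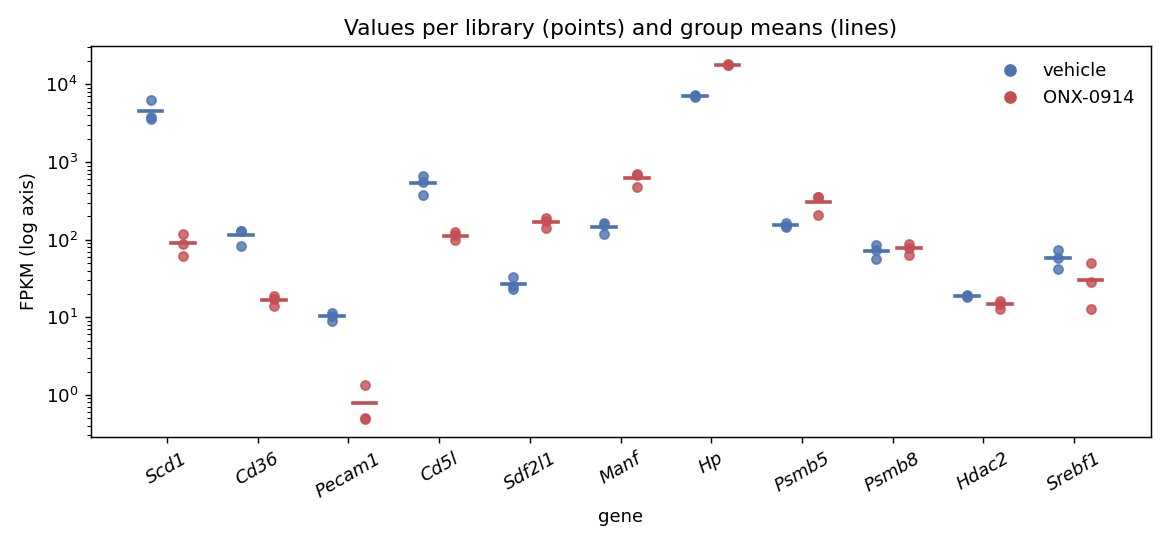
FPKM on a log axis for 11 genes in each of the 3 vehicle and 3 ONX-0914 libraries (points) with group means (lines). Scd1 averaged 4580 with vehicle and 89.7 with ONX-0914, while the points of Psmb8 and of Srebf1 overlap between the groups.

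The gene of the drug's target did not pass the test, while the genes of 2 constitutive catalytic subunits rose. Psmb8, on chromosome 17 from 34197721 to 34201454 of GRCm38, was 55.6, 84.7 and 73.1 FPKM in vehicle 1, 2 and 4 and 89.0, 62.7 and 79.1 in ONX-0914 1, 3 and 4 (log2 fold change 0.12, SE 0.23, limma adjusted p = 0.688). Psmb8 was at 0.71 scaled by median ratio (adjusted p = 0.088) and at 0.49 with the length trend removed (adjusted p = 0.169). Psmb9 had a log2 fold change of -0.36 (adjusted p = 0.253) and Psmb10 one of 0.32 (adjusted p = 0.24). Psmb10 passed the test scaled by median ratio (0.91, adjusted p = 0.0322). The constitutive subunits Psmb5 and Psmb6, which Psmb8 and Psmb9 replace in the immunoproteasome, rose, with log2 fold changes of 0.94 (SE 0.24, adjusted p = 0.0131) and 1.111 (SE 0.28, adjusted p = 0.0122). They were at 1.54 and 1.71 scaled by median ratio, and in ONX-0914 3 alone against vehicle at 0.43 and 0.49 (adjusted p = 0.0915 and 0.119). Psmb7 had a log2 fold change of 0.40 (adjusted p = 0.133) and passed scaled by median ratio (0.99, adjusted p = 0.0278). Of 37 constitutive proteasome genes, 6 rose and 4 fell over all genes, 4 and 3 adjusted over the list alone, with a median log2 fold change of 0.00, so the camera call (adjusted p = 1.27e-07, or adjusted p = 0.263 with an estimated correlation) was a rise relative to other genes. Scaled by median ratio 17 rose and 1 fell, and with the length trend removed 12 rose and 1 fell. Of 23 immunoproteasome and antigen presentation genes, 5 fell and none rose (4 and none adjusted over the list alone). The direction depended on the scaling: by median ratio 1 fell and 6 rose, with a median of 0.46, and with the length trend removed 1 fell and 1 rose (camera adjusted p = 0.136). As deposited their median was -0.12 while camera placed the list above other genes (adjusted p = 0.0222, or adjusted p = 0.317 with an estimated correlation).

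Hdac2, which encodes a histone deacetylase and lies on chromosome 10 from 36974544 to 37001889, was 19.1, 18.6 and 18.4 FPKM in vehicle 1, 2 and 4 and 16.4, 14.98 and 12.8 in ONX-0914 1, 3 and 4. Its log2 fold change of -0.33 (SE 0.22, limma adjusted p = 0.225) became 0.23 scaled by median ratio (adjusted p = 0.402). RNA values carry no information on HDAC2 protein or on SREBP1 acetylation.

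Sdf2l1 went from 27.1 ± 5.44 to 168 ± 23.4 FPKM (n = 3 each, log2 fold change 2.59, SE 0.22, limma adjusted p = 0.000811, or 3.18 scaled by median ratio), and Manf from 144 ± 22.7 to 617 ± 122 (log2 fold change 2.08). Calr and Creld2 had log2 fold changes of 1.44 and 2.26, and Fkbp11 and Dnajc12, outside the list, 2.39 and 2.31. Of 31 unfolded protein response and heat shock genes, 10 rose, 2 fell and 19 were not called, over all genes and adjusted over the list alone, with a median of 0.37 (0.90 scaled by median ratio, where 14 rose and 2 fell, and 0.99 with the length trend removed, where 17 rose and none fell). The camera adjusted p was 1.16e-14, and adjusted p = 0.317 with an estimated correlation.

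Among the acute-phase genes, whose products hepatocytes secrete in inflammation, Hp went from 7036 ± 198 to 17900 ± 510 FPKM (n = 3 each, log2 fold change 1.35, or 1.95 scaled by median ratio), and Apcs, serum amyloid P, from 710 ± 68.0 to 3353 ± 1203. Lcn2 and Mt2 had log2 fold changes of 1.76 (SE 0.28) and 2.32 (SE 0.47). Mt2 did not pass with the length trend removed (1.96, adjusted p = 0.0511). Of 28 list members, 11 rose, 1 fell and 16 were not called, over all genes and adjusted over the list alone, with a median of 0.78 (1.38 scaled by median ratio and 0.96 with the length trend removed, where 14 rose in each and none fell). Those not called included Saa1 (0.05, limma adjusted p = 0.95), Saa2 (0.79, adjusted p = 0.345), Saa3 (-0.02, adjusted p = 0.965) and Crp (-0.999, adjusted p = 0.112). The camera adjusted p was 2.06e-15, and adjusted p = 0.0835 with an estimated correlation. Among the 10 named rises the largest log2 fold change was that of Cxcl14, a chemokine, from 9.21 ± 2.43 to 114 ± 62.6 FPKM (3.31, SE 0.46). That order depends on the value of 1 added before the log, which shrinks changes of low genes. Crybb3 went from 1.61 to 25.8 FPKM (2.99). Among 42 interferon-stimulated genes 23 fell and 1 rose, and among 24 cytokine and NF-kB genes 10 fell and none rose, and camera called neither list (adjusted p = 0.997 and 0.634). Scaled by median ratio 12 interferon-stimulated genes fell and 7 rose, and with the length trend removed 4 fell and 4 rose. Of the cytokine and NF-kB genes 3 fell and 1 rose in the former, and 4 fell and 1 rose in the latter.

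Markers of cells other than hepatocytes moved unequally. All 24 tested markers of endothelial cells, which line the liver's vessels and sinusoids, fell over all genes and adjusted over the list alone, with a median log2 fold change of -1.77 (-1.38 scaled by median ratio, where 22 fell, and -0.99 with the length trend removed, where 18 fell). The camera adjusted p was 9.07e-09, and adjusted p = 0.317 with an estimated correlation. Cdh5 went from 9.46 ± 1.87 to 0.76 ± 0.361 FPKM and Dnase1l3 from 21.5 ± 2.20 to 1.31 ± 1.01 (n = 3 each), and Aqp1 had a log2 fold change of -3.89 (SE 0.43, or -3.46 scaled by median ratio). Of 26 fibrosis and matrix genes 20 fell and none rose (22 and none adjusted over the list alone), among them Sparc (-3.20, SE 0.25), and 12 fell and 1 rose scaled by median ratio, and 7 fell with the length trend removed. Their camera adjusted p was 0.00286, and adjusted p = 0.649 with an estimated correlation. Of 19 Kupffer cell markers 10 fell, none rose and 9 were not called. Cd5l fell (-2.19), while Clec4f (-0.0078, limma adjusted p = 0.988) and Marco (0.14, adjusted p = 0.815) were not called. Of 23 markers of monocyte-derived and lipid-associated macrophages 13 fell and 1 rose, the former including Gpnmb (-3.73) and Clec7a (-3.19). Camera called neither macrophage list (adjusted p = 0.482 and 0.898). With the length trend removed 8 Kupffer cell markers fell (camera adjusted p = 0.0255, or adjusted p = 0.669 with an estimated correlation), and 6 markers of the other macrophage list fell and 1 rose (camera adjusted p = 0.0682). The counts scaled by median ratio were 5 Kupffer cell markers lower, and 6 of the other list lower and 3 higher. In ONX-0914 3 alone against vehicle camera placed both lists below other genes (adjusted p = 0.00611 and 0.0145, or adjusted p = 0.639 and 0.673 with an estimated correlation). Of 23 stellate cell and fibroblast markers 13 fell and none rose (camera adjusted p = 0.09), and 6 fell and 1 rose with the length trend removed (camera adjusted p = 0.0255, or adjusted p = 0.512 with an estimated correlation). Scaled by median ratio 9 of these markers fell and 1 rose (camera adjusted p = 0.0356). Krt8 and Krt18, keratins of cholangiocytes that hepatocytes also express, rose by 1.47 and 1.38. Of 26 hepatocyte markers 4 rose and 5 fell, the latter including Hnf4a (-2.23, SE 0.59). Hnf4a was at 6.26, 40.7 and 5.94 FPKM in ONX-0914 1, 3 and 4, against a vehicle mean of 59.6. In ONX-0914 3 alone against vehicle its log2 fold change was -0.53. The 5 falls among hepatocyte markers did not pass in 2 other settings: 8 rose and none fell scaled by median ratio (Hnf4a -1.67, adjusted p = 0.0513), and 7 rose and none fell with the length trend removed. Camera placed hepatocyte, neutrophil, T and NK cell, B and plasma cell and cholangiocyte markers above other genes (adjusted p = 4.77e-05, 8.15e-06, 0.00354, 0.0306 and 0.00403). With an estimated correlation these were adjusted p = 0.263, 0.339, 0.263, 0.317 and 0.263. With the length trend removed camera no longer called the last 4 (adjusted p = 0.106, 0.51, 0.634 and 0.15). Their medians were 0.05, 0.49, 0.14, -0.34 and -0.13. Of 16 neutrophil markers 1 rose and none fell, of 12 T and NK cell markers none rose and 1 fell, of 11 B and plasma cell markers 1 rose and 1 fell, and of 12 cholangiocyte markers 3 rose and 3 fell. The cholangiocyte counts were 5 higher and 1 lower scaled by median ratio, and 3 higher and none lower with the length trend removed. The neutrophil median was -0.97 in ONX-0914 3 alone against vehicle.

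**Figure D2:**
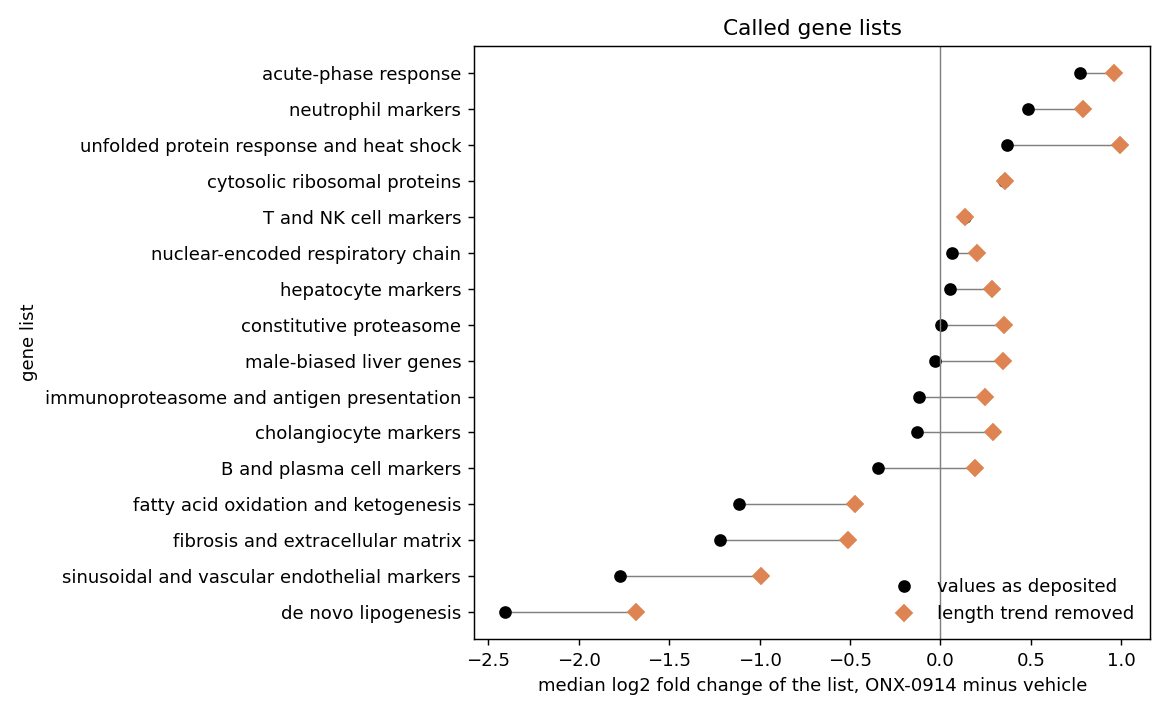
Median log2 fold change (ONX-0914 minus vehicle) of each list that camera called and whose members have a transcript length, from the values as deposited (circles) and after each library's length trend was removed (diamonds). De novo lipogenesis moves from -2.41 to -1.68 and endothelial markers from -1.77 to -0.99.

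Over all 10743 genes, limma-trend with Benjamini-Hochberg adjustment called 275 genes higher and 4673 lower with ONX-0914. Scaled by median ratio the split was 1036 higher and 2007 lower, and after quantile normalization 1118 and 1334. Camera called 17 of 37 lists with the preset correlation and 0 with an estimated one. The latter test has few degrees of freedom with 6 libraries. Its smallest unadjusted p was 0.00226, for the acute-phase list, so its lack of calls is weak evidence against any list. The treated libraries also differed by transcript length. The median log2 difference from vehicle of the longest 25% of transcripts, minus that of the shortest 25%, was -0.95, -0.26 and -0.995 in ONX-0914 1, 3 and 4, against 0.06, -0.01 and -0.05 in vehicle 1, 2 and 4. With that trend removed, 1007 genes were higher and 1240 lower. The count of higher genes was 92, 124 and 111 without vehicle 1, 2 and 4, and 141, 740 and 134 without ONX-0914 1, 3 and 4. The count of lower genes was 2590, 2840 and 2966 without vehicle 1, 2 and 4, and 3197, 6514 and 3025 without ONX-0914 1, 3 and 4.

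**Figure D3:**
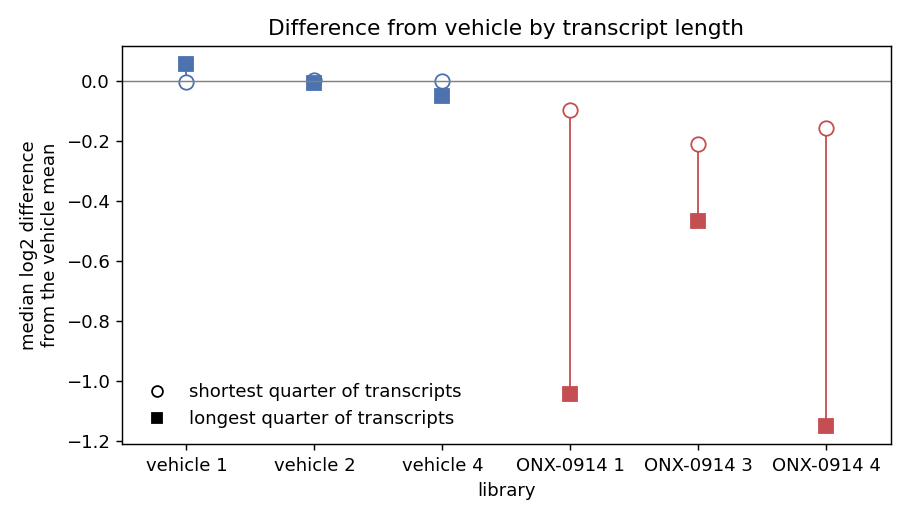
Median log2 difference from the vehicle mean for the shortest 25% (open circles) and longest 25% (squares) of transcripts in each library. The circle and square lie close together in each vehicle library (0.06, -0.01 and -0.05) and differ by -0.95, -0.26 and -0.995 in ONX-0914 1, 3 and 4.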

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

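The scalings, the trend removals, ONX-0914 3 alone, the robust fit and the filter on the mean were chosen after the data were seen. Planned count-based settings (scaling factors in a count model, other count tests, a CPM filter) were not run, as the values are not counts. Absolute depth is unknown. Simulated changes of 0.5 on the log2 scale were all missed, but few genes changed in those data. That made the cutoff on p stricter there, so the shares recovered do not carry over. Here changes under 1 were called too, among them Psmb5 (0.94) and Psmc2 (0.60).

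Genes higher numbered 275 and lower 4673. They were 110 and 3062 with an absolute log2 fold change of at least 1, 1036 and 2007 scaled by median ratio, 814 and 2349 by upper quartile, 1118 and 1334 quantile normalized, 1007 and 1240 with the length trend removed, and 1001 and 1212 with length and GC trends removed. With equal sums 172 were higher. Fewer were lower with ONX-0914 3 alone (2992, fewer samples, with the spread from vehicle only) and with a mean of at least 10 (1619, fewer genes). Leaving out each library gave 92 to 740 higher and 2590 to 6514 lower, and 16 to 20 lists. Where no cause is given, the cause was not tested. Called lists numbered 17, and 0 with an estimated correlation, 20 with fry. Of the 14 called with the length trend removed 10 were among the 17, and of the 21 called quantile normalized 11. An estimated correlation also gave 0 with the length trend removed and 0 with ONX-0914 3 alone, both chosen after the data were seen.

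The replicate numbers gave no clear pairing: deviations of vehicle 1 and ONX-0914 1 correlated at 0.001. Those of vehicle 4 and ONX-0914 4 correlated at 0.133, the highest value, but vehicle 4 and ONX-0914 1 came close at 0.102. The replicate block gave 604 genes higher. Of 151 genes the naming rule gave, 143 were called, of which 25 did not pass scaled by median ratio and 37 of the 141 with a length value did not pass with the length trend removed.

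These log2 fold changes turned in sign and none passed the test after turning. Leaving out each library, Psmb8 ran from -0.0467 (without vehicle 1) to 0.26. With equal sums, Psmb8 was at -0.0378. With ONX-0914 3 alone, Psmb8 was at -0.16, Cela2a was at -0.0434, Cela1 was at 0.29. Scaled by median ratio, Psmb9 was at 0.22, Hdac2 was at 0.23, Atp5a1 was at 0.092, Cela1 was at 0.22. By upper quartile, Psmb9 was at 0.14, Hdac2 was at 0.16, Atp5a1 was at 0.00863, Cela1 was at 0.14. Quantile normalized, Psmb9 was at 0.0861, Hdac2 was at 0.30, Nr4a1 was at 0.17, Cela1 was at 0.34. With the length trend removed, Hdac2 was at 0.45, Top2a was at 0.0101, Atp5a1 was at 0.18, Nr4a1 was at 0.0358. With length and GC trends removed, Hdac2 was at 0.55, Top2a was at 0.12, Atp5a1 was at 0.12. The cause was not tested.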

Other observations

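The tests of the length trend on the 2 gene lists and the splits of the libraries were set before their results were seen. The comparison of the longest with the shortest transcripts, the medians per library, the cell share tests, the list tests with an estimated correlation after the length trend was removed and the fasting test were chosen after.

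Of 24 bile acid genes 14 fell and 1 rose, among them Akr1d1 (log2 fold change -3.17, SE 0.31, limma adjusted p = 0.000986) and Cyp8b1 (-2.23), both enzymes of bile acid synthesis (camera adjusted p = 0.0834), and 8 fell and 1 rose scaled by median ratio. Of 28 xenobiotic genes 13 fell and 2 rose, including Cyp2c29 (-2.10) and Nr1i3 (-1.42), the gene of the nuclear receptor CAR, and 8 fell and 4 rose scaled by median ratio. Of 25 gluconeogenesis, glycolysis and insulin genes 14 fell and 1 rose, including Slc2a2 (-2.90), the liver glucose transporter, and 4 fell and 4 rose scaled by median ratio. Camera gave both lists an adjusted p of 0.997. Of 14 female-biased genes 9 fell and none rose (camera adjusted p = 0.0507), and of 30 male-biased genes 5 rose and 4 fell, 0 and 1 adjusted over the list alone. Scaled by median ratio 8 female-biased genes fell and none rose, and 10 male-biased genes rose and 1 fell. With the length trend removed these were 6 and none, and 6 and 1. Camera placed the female-biased list below other genes scaled by median ratio (adjusted p = 0.0146) and with the length trend removed (adjusted p = 0.00485). The latter became adjusted p = 0.256 with an estimated correlation. The male-biased list had a median of -0.03 and was called up by camera (adjusted p = 2.76e-06, or adjusted p = 0.601 with an estimated correlation), but not with the length trend removed (adjusted p = 0.101).

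Of 20 periportal hepatocyte genes 11 fell and none rose, among them Uroc1 (-1.66), and of 21 pericentral genes 12 fell and 1 rose, among them Glul (-1.49). Camera called neither zone list (adjusted p = 0.635 and 0.399). The periportal counts were 4 lower and 3 higher scaled by median ratio and 2 lower and 2 higher with the length trend removed, and the pericentral ones 5 lower and 1 higher in both. Of 28 genes of histone deacetylases, acetyltransferases and SREBP processing 14 fell and none rose (camera adjusted p = 0.399). That is near the share over all genes, where 4673 of 10743 were lower. With the length trend removed 2 of the 28 fell and 1 rose. Of 27 NRF2 and glutathione genes 8 fell and 1 rose, but 3 fell and 4 rose both scaled by median ratio and with the length trend removed. Of 20 immediate-early genes 2 fell, but none adjusted over the list alone, and none fell in these other settings, where 1 and 2 rose. Of 12 erythroid genes 4 fell (2 and 1 in these settings), of 8 adipocyte genes 4 fell (4 lower and 1 higher in each), and none of 3 pancreatic genes was called. Of 19 clock genes 9 fell and none rose, and of 26 cell cycle genes 12 fell and none rose (camera adjusted p = 0.898 for each). Scaled by median ratio 4 clock genes fell and 1 rose, and 2 cell cycle genes fell and 2 rose. With the length trend removed 2 clock genes fell and none rose (median 0.01), and none of the cell cycle genes fell and 4 rose (median 0.26). Of 75 ribosomal protein genes 12 rose and none fell, 0 adjusted over the list alone (camera adjusted p = 9.78e-29, or adjusted p = 0.317 with an estimated correlation), while 56 rose scaled by median ratio and 15 with the length trend removed. Of 40 nuclear respiratory chain genes 3 rose and 5 fell (0 and 3 adjusted over the list alone), and of 13 mitochondrially encoded genes 2 rose and none fell. In median-ratio scaled values 12 nuclear ones rose and 2 fell, and 4 mitochondrial ones rose. With the length trend removed 4 nuclear ones rose and 2 fell. As deposited, camera called both lists up (adjusted p = 2.77e-07 and 8.15e-06, or adjusted p = 0.317 for each with an estimated correlation), with medians of 0.06 and -0.03.

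More genes were lower than higher with ONX-0914. A few abundant transcripts taking more of the values, as the whole cause, would shift all lengths alike. However, the longest 25% minus the shortest 25% of transcripts averaged -0.732 over the treated libraries, beyond any vehicle library. As part of the cause it stays open. The top 200 genes held 70.8, 66.9 and 73.0% of the values in ONX-0914 1, 3 and 4. In vehicle 1, 2 and 4 they held 59.3, 59.6 and 62.3%. A length trend in the treated libraries, as degraded RNA may give, stays open: the 2 length classes differ by -0.255 in the treated library nearest 0, but that difference prompted the explanation, and the shortest 25% were lower as well (-0.096, -0.21 and -0.155 in ONX-0914 1, 3 and 4). RNA integrity values were not used here, and a change of long transcripts by the drug itself stays open, untested. Of the 10 splits of the 6 libraries, too few for a share under 0.05, the real one gave 275 genes higher and 4673 lower (1 of 10 splits each), and the highest other gave 0. For the lists, 3 of 10 splits gave as many as the real 17 and the highest other gave 18. However, all other splits put vehicle and treated libraries together in each group. They thus kept part of the treatment difference and added the rest to the spread within groups. Their 0 genes and their list counts therefore do not show what libraries without a treatment difference would give. The real split did not give the most lists, so the number that camera calls with the preset correlation is no evidence for the treatment either.

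Endothelial markers were lower. The length trend as the whole cause is argued against by their median of -0.99 after its removal, where 18 of 24 markers still fell, and by medians of -0.858, -1.18 and -1.27 in ONX-0914 1, 3 and 4 against -0.0243, 0.0101 and 0.034 in vehicle 1, 2 and 4 (camera adjusted p = 3.87e-11, but adjusted p = 0.256 with an estimated correlation). A lower share of all non-hepatocyte cells alike is argued against too, but only as far as the markers stand for their cells. Among markers with a vehicle mean of at least 5 FPKM, 68 of the 7 other types had a median of -0.27. The endothelial median lay -1.22 from theirs (permutation p = 1e-04), and -1.39, -0.696 and -1.44 in ONX-0914 1, 3 and 4. Without the 7 neutrophil markers (medians of 0.98, -1.5 and 2.23 in these libraries) it lay -1.16 away, and cutoffs of 0, 2 and 10 gave differences of -0.965, -0.911 and -1.24, while Kupffer cell, other macrophage and stellate cell markers had medians of -0.616, -0.63 and -0.3. Each permutation p here treats markers as independent, whereas the endothelial list had an estimated correlation of 0.439 in the values as deposited. These p are then too small, and only the differences bear on the question. The 68 markers held Krt8 and Krt18 (1.97 and 1.65), which hepatocytes also express. Only 2 T and NK and 3 B and plasma cell markers were among them. Whether hepatocytes express others of the 68 was not checked, and such markers could hide a fall. Single markers also differed: Cd5l (-1.67) and Gpnmb (-2.89) fell past the endothelial median of -1.49, while Clec4f and Marco were each at 0.63. The test with 7 types was added after a first comparison, with Kupffer cell markers, had missed its threshold (difference -0.374, permutation p = 0.0839). With the cutoff of 5 that comparison gave -0.875 (permutation p = 0.0051). A lower share of endothelial and Kupffer cells together stays open, since these cutoffs disagree and camera placed the Kupffer list below other genes with the preset correlation (adjusted p = 0.0255) but not with an estimated one (adjusted p = 0.669), as does lower expression in these cells, which was not tested.

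De novo lipogenesis genes were lower. The length trend as the whole cause is argued against by their median of -1.68 after its removal, with 18 of 25 genes still lower, and by medians of -2.03, -1.57 and -1.73 in ONX-0914 1, 3 and 4 against 0.404, -0.0535 and -0.369 in vehicle 1, 2 and 4 (camera adjusted p = 8.9e-11, but adjusted p = 0.256 with an estimated correlation). Fasting before the livers were taken could lower them too and would raise fasting-induced genes. Of 15 such genes 14 were tested, and their median length-corrected log2 fold change was -0.223, with 4 above and 10 below 0. The p of 0.0443 with the preset correlation became p = 0.422 with an estimated one, so fasting stays open, as does the drug treatment itself. That both p should pass was required only after the first had been seen.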
